A study of Brassica rapa subsp. pekinensis with 10 samples.

How the data were processed

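Total RNA of Chinese cabbage (Brassica rapa subsp. pekinensis) was hybridised to one-colour Cy3 NimbleGen oligonucleotide arrays, per the labels' protocols. The 10 arrays covered 2 varieties, Man-Su and Shin-Hong. Each variety had an array labelled normal and arrays labelled cold for 15, 30, 60 and 120 min, with 1 array in each of the 10 groups. The tissue, the temperature and the age of the plants are not given in the sources used here.

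The deposited values are linear intensity values per feature, made by the authors with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a feature), per the submitters' processing notes. The RMA software, its version and whether all arrays were normalized together are not given in the sources used here. The deposited files also give the number of probes per feature, as another kind of value, per the file headers. Of 47548 cabbage features, 46793 (98.4%) had 7 probes and the others 3 to 6. A further 6 features were controls: 5 barcode sequences and 1 random-sequence control summarised over 57777 probes. The controls were left out of normalization and tests and were read as a measure of array background. A series-wide table by the authors held the same intensity values to within 0.005.

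The intensities were taken to log2. No filter was applied. A rule set before the data were examined called for quantile normalization over all arrays if the mean deciles of normal and cold arrays were over 0.1 log2 units apart. The largest gap was -0.11 (normal minus cold, decile 2), so the values used were quantile normalized over the 10 arrays, and the deposited values became an alternative.

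Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all 47548 features. The cold times against normal and the varieties over all arrays came from a fit of treatment and variety with 4 residual degrees of freedom. With 1 array per group, the spread came from the variety-by-treatment differences, and the p-values treat the 2 varieties as the samples of a treatment. Nothing in the labels says whether the arrays came from separate plants or pools, so the spread may be partly technical. In this balanced fit the change of a feature against normal is the same whichever variety the normal arrays are given, and the labels act on its error. The varieties were also compared in the 8 cold arrays alone, with time as a block and 3 residual degrees of freedom. The time trend was the slope per doubling of cold time in the 8 cold arrays, with variety as a term and 5 residual degrees of freedom. The variety by cold interaction used the 4 cold arrays of a variety as its samples and had 6 residual degrees of freedom. It assumed that the lone normal array of each variety varied like them. The variety by time interaction was the difference of the slopes, with 4.

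The tests were tried on simulated data with 100 changed features of each size among 47548. For all cold against normal, the simulation used the variety labels of the normal arrays exchanged, an alternative described below. There 38% of changes of 1 log2 unit and 78% of changes of 2 units were recovered, with 5 false calls. Recovery with the labels as given was not simulated and may be lower, since that fit called 906 features and the exchanged one 7137. For the varieties in cold the shares were 37% and 83%, with 3 false calls. For the time trend they were 31% and 73%, with 4. The sizes simulated for the trend were changes over the whole span of cold times, not slopes per doubling. With no change simulated, none of these 3 tests called a feature. The simulated noise was independent between features and arrays, so false calls from array effects shared across features were not covered.

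A check of the variety labels was fixed before the data were examined: the 50 features with the widest gap between the arrays labelled Shin-Hong cold and those labelled Man-Su cold were read in the normal arrays. The titles of the samples give the normal arrays letters that go with the opposite variety in the cold arrays, so a fit with the variety labels of the normal arrays exchanged was also set beforehand.

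The files do not pair feature IDs with gene names. The gene information column was empty for all features, and 0 IDs matched the gene name table used here, of assembly CAAS_Brap_v3.01. The 20 gene lists fixed beforehand could therefore not be tested, and no gene is named. The naming rule took the features with the largest rises and falls among those called with the same direction in both varieties. For the varieties in cold it took those with the same direction at every cold time. It also asked for a gene name, which was dropped because none has one, and 2 IDs per direction are printed, for all cold against normal. Features of the other comparisons are described without their ID.

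Alternatives set beforehand were the deposited values, median centring, leaving out the dimmest 25% of features, an intensity trend in the prior variance, a threshold of 2-fold, the series-wide table, the exchanged labels, no block, minutes in place of log2 minutes, and each array left out. A term for the level of the control features and fits without arrays that stood apart were added after the data were seen. Array number limits the precision of every value.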

Results

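Transcript levels of 47548 features were measured in 10 arrays of Chinese cabbage, a leafy Brassica rapa crop. The series followed 2 varieties, Man-Su and Shin-Hong, through a short time course of cold stress. For each variety there was 1 array labelled normal and 1 array at each of 15, 30, 60 and 120 min of cold, so no group had a replicate. Median intensity lay between 12.02 and 12.08 log2 units in the 10 arrays before quantile normalization, and the random-sequence control lay between 5.13 and 5.74.

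The first question was how the varieties differed. In the 8 cold arrays, 6174 features were higher and 6021 lower in the arrays labelled Shin-Hong than in those labelled Man-Su, 25.6% of those tested. The median difference of the called features was 1.68-fold. Of the called features, 1838 were at least 2-fold higher and 1404 at least 2-fold lower. In 117 features each array labelled Shin-Hong cold exceeded each array labelled Man-Su cold by over 4-fold, and in 84 the reverse held. These margins were taken on the normalized values, without a floor for dim signal. Chance order alone would part the 4 and 4 arrays, by any margin, in 2.86% of features. That share assumes exchangeable arrays, and the counts at over 4-fold cannot be set against it.

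The largest fitted differences were between bright signal and background. They were ordered by dim values below the random-sequence control, so this order is no rank of true size, and other features have larger bounds. The feature with the largest fitted excess in the arrays labelled Shin-Hong cold had 13.15 ± 0.61 log2 units there (SD, n = 4) and 4.01 ± 0.71 in the arrays labelled Man-Su cold (SD, n = 4). Its difference was 9.14 ± 0.24 log2 units (SE, limma adjusted p = 9.71e-06). The dim side lay below the random-sequence control, so the deposited values give a bound, and this feature was at least 224-fold higher. Another such feature was at least 149-fold higher, with 12.54 ± 0.24 against 4.30 ± 0.37 (SD, n = 4 each). For the 2 features with the largest fitted excess in the arrays labelled Man-Su cold, signal there was at least 80.1-fold and at least 61.4-fold higher. All these folds are bounds on array signal, and whether transcript levels differed as much between the varieties was not tested. All 4 features differed in the same direction at each of the 4 cold times, which the naming rule required of them. Leaving out either 60 min array lowered the count of called features from 12195 to 2989, and leaving out either 15 min array to 3373. With a term for the control-feature level, which was high in the 4 arrays labelled Shin-Hong cold and in Man-Su cold 30 min, 534 features were called, and the difference then rested on the 30 min pair.

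The arrays labelled normal did not keep these variety differences. Of the 50 marker features, 27 were higher in the arrays labelled Shin-Hong cold and 23 in those labelled Man-Su cold. On the normalized values the nearest arrays were at least 12.8-fold apart for each. Dim sides of many markers lay below the random-sequence control, so this gap is no bound on the true fold. In the normal arrays 0 of the 50 kept the labelled direction. The 27 averaged 11.24 ± 1.75 log2 units in the array labelled Man-Su normal and 6.30 ± 1.77 in the array labelled Shin-Hong normal (SD over features). Their averages were 11.45 to 11.87 in the arrays labelled Shin-Hong cold and 5.54 to 6.19 in those labelled Man-Su cold. The 23 averaged 4.63 ± 1.21 in the array labelled Man-Su normal and 10.73 ± 1.57 in the array labelled Shin-Hong normal. Of the 201 features that were over 4-fold apart in every cold array, 0 kept the labelled direction, and of the 12195 called features 17.4% did. Across features, which are not independent replicates, the array labelled Man-Su normal correlated at 0.941 to 0.963 with the arrays labelled Shin-Hong cold and at 0.929 to 0.931 with those labelled Man-Su cold. The array labelled Shin-Hong normal correlated at 0.934 to 0.957 with the arrays labelled Man-Su cold and at 0.90 to 0.907 with those labelled Shin-Hong cold.

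**Figure D1:**
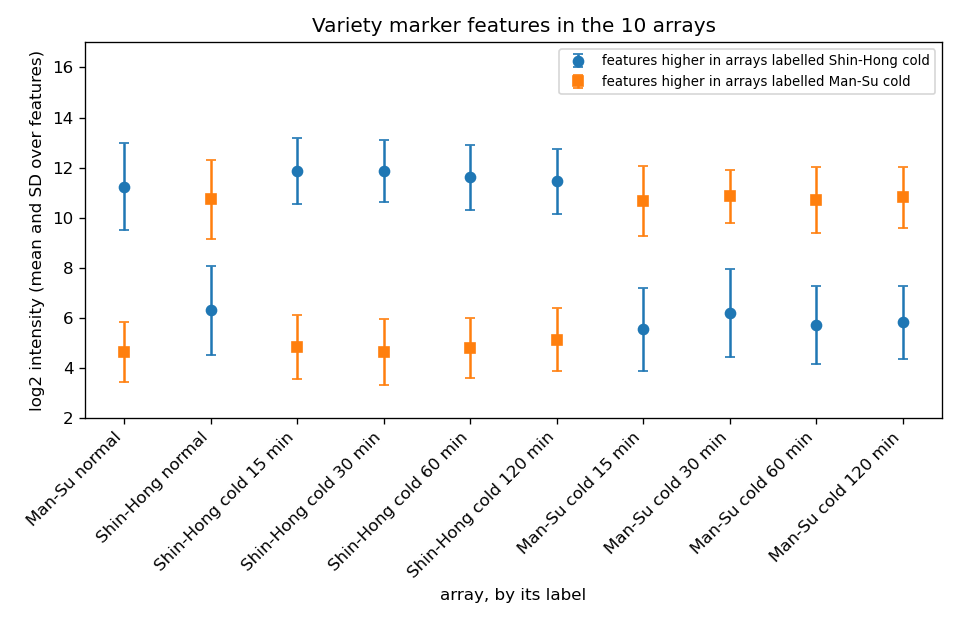
Mean log2 intensity of the 27 features higher in arrays labelled Shin-Hong cold (circles) and the 23 higher in arrays labelled Man-Su cold (squares), for each of the 10 arrays by its label; bars are SD over features. The array labelled Man-Su normal has the 27 at 11.24 and the 23 at 4.63, as in the arrays labelled Shin-Hong cold, and the array labelled Shin-Hong normal has 6.30 and 10.73.

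Over all 10 arrays with the labels as given, limma called 0 features between the varieties, while 7122 had an unadjusted p under 0.05. With the variety labels of the normal arrays exchanged, 6064 were higher and 6323 lower in Shin-Hong. The interaction of variety and cold called 6081 features with the labels as given, 3158 with a cold minus normal change that was more positive in the arrays labelled Shin-Hong than in those labelled Man-Su and 2923 with one that was more negative. With the labels exchanged limma called 0, with 4589 at an unadjusted p under 0.05. Any statement on a variety against its own normal array therefore depends on which labels are taken.

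The second question was how cold changed transcript levels against normal. Averaged over the 4 cold times, 610 features rose and 296 fell with the labels as given. The same changes with the labels exchanged gave 3862 rises and 3275 falls, and 897 features were called both ways. On the deposited values the exchanged labels gave 4222 rises and 1820 falls. Without reference to variety, 129 features were at least 2-fold higher in each of the 8 cold arrays than in either normal array, and 26 were at least 2-fold lower. Features without any overlap between the 8 and the 2 arrays made up 21.5% of those tested. Chance order would give 4.44% if all arrays were exchangeable. They were not, since the cold arrays of a labelled variety resembled one another, so the 2 shares make no test.

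By the naming rule, the largest rises were in Brapa_ESTC006798 and Brapa_ESTC018709. Brapa_ESTC006798 rose by 3.77 ± 0.27 log2 units (SE), or 13.7-fold, from 8.60 and 9.53 in the arrays labelled Man-Su normal and Shin-Hong normal to 12.84 ± 0.33 in cold (SD, n = 8; limma adjusted p = 0.0204). Brapa_ESTC018709 rose by 3.57 ± 0.30 log2 units (SE), or 11.9-fold, to 13.68 ± 0.48 (SD, n = 8; limma adjusted p = 0.0204). Among the features that fell, Brapa_ESTC017928 fell by 2.06 ± 0.24 log2 units (SE), or 4.16-fold, to 10.87 ± 0.32 (SD, n = 8; limma adjusted p = 0.0265). Brapa_ESTC002401 fell by 2.05 ± 0.24 log2 units (SE), or 4.14-fold, to 10.27 ± 0.62 (SD, n = 8; limma adjusted p = 0.0268). With the labels exchanged the adjusted p of these features lay between 0.000664 and 0.00572. In all 8 cold arrays the 2 that rose stood above both normal arrays and the 2 that fell stood below them. The calls with the labels as given were fragile: leaving out any single cold array, or adding the control-level term, left 0 features called. With a cold array left out the changes themselves stayed about as large. The difference of Brapa_ESTC006798 from normal was then 3.66 to 3.89 log2 units (SE 0.23 to 0.30, limma adjusted p 0.0572 to 0.104) and 3.98 ± 0.39 with the control-level term (SE, limma adjusted p = 0.257). For Brapa_ESTC018709 these were 3.49 to 3.66 (SE 0.30 to 0.33, limma adjusted p 0.0659 to 0.104) and 3.19 ± 0.39 (SE, limma adjusted p = 0.257). Leaving out a normal array moved them more. Such a fit sets the cold arrays of the remaining normal array's labelled variety against that array alone. Its value thus carries the variety labels in doubt and is no measure of the normal array's weight. Brapa_ESTC018709 stood 4.18 log2 units above normal without the array labelled Man-Su normal and 2.97 without the array labelled Shin-Hong normal. Brapa_ESTC006798 stood at 3.43 and 4.12. On the deposited values the split was 760 rises to 204 falls.

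At single times the same 2 normal arrays served every comparison, so the times are not independent of one another. With the labels as given, limma called 1 feature at 15 min, 2 at 30 min and 3 at 60 min, all higher in cold. At 120 min it called 114 higher and 9 lower. The feature called at 15 min was also called at 30 and 60 min, with rises of 3.44, 3.58 and 3.33 log2 units (SE 0.20). Unadjusted p under 0.05 was reached by 7266, 9090, 6059 and 9640 features at 15, 30, 60 and 120 min. With the labels exchanged the counts were 1447, 3434, 723 and 3457. Brapa_ESTC006798 stood 3.79, 3.85, 3.50 and 3.96 log2 units above normal at 15, 30, 60 and 120 min (SE 0.34), with limma adjusted p of 0.059, 0.0555, 0.086 and 0.0393 with the labels as given, a call at 120 min alone. With the labels exchanged its limma adjusted p was 0.0093, 0.00745, 0.0132 and 0.00533, a call at each of the 4 times. Both cold arrays were at least 2-fold above both normal arrays for 368, 613, 319 and 770 features at these times, and at least 2-fold below for 139, 171, 76 and 317. Chance order would part 2 and 2 exchangeable arrays, by any margin, in 33.3% of features, so the counts at 2-fold cannot be set against that share. The larger counts fell at the 2 times that hold an array leaning towards the other variety. At features under 1 log2 unit apart between the varieties, Man-Su cold 30 min lay 34.4% of the way towards the arrays labelled Shin-Hong cold, and Shin-Hong cold 120 min lay 50.3% of the way towards those labelled Man-Su cold. At features over 4 log2 units apart these were 6.71% and 8.98%. Leaving out any cold array brought the count at 120 min to 2 or fewer.

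**Figure D2:**
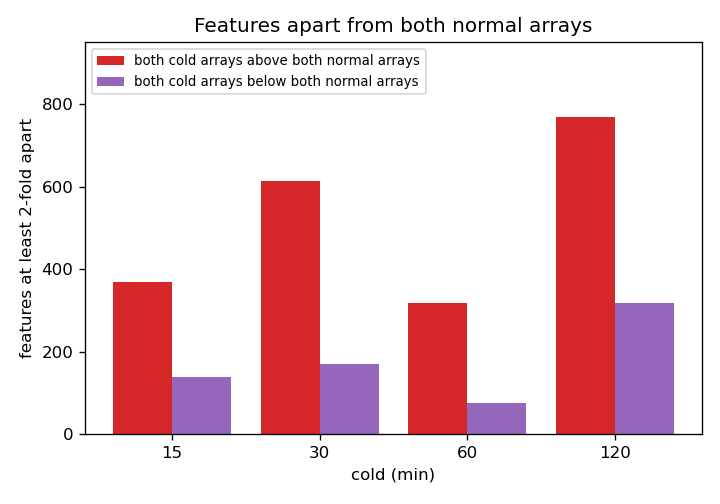
Number of features (y axis) for which both arrays of a cold time (x axis, min) were at least 2-fold above both normal arrays (red) or below them (purple). The number above was 368 at 15 min and 770 at 120 min, with fewer at 60 min (319) than at 30 min (613); the 30 and 120 min pairs each hold an array that leaned towards the other variety.

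The third question was which features changed with the length of cold, which needs no normal array. In the 8 cold arrays 70 features rose and 22 fell with time. The steepest rise was 1.53 ± 0.14 log2 units per doubling of time (SE, n = 8; limma adjusted p = 0.0200), or 24.3-fold from 15 to 120 min. That feature stood at 7.27, 7.96, 9.92 and 12.31 log2 units in the arrays labelled Shin-Hong at 15, 30, 60 and 120 min and at 8.47, 9.84, 10.42 and 12.81 in those labelled Man-Su. The steepest fall was 0.86 ± 0.10 log2 units per doubling (SE, n = 8; limma adjusted p = 0.0305), or 6.02-fold over the same span. Of the 70 that rose, 54 increased at every step in both varieties, and of the 22 that fell, 15 decreased at every step in both. These features were chosen for their slope over the same arrays, which favours such an order.

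The features that rose were near normal at 15 min and above it at 120 min. Their median stood at -0.27 log2 units from the mean of the normal arrays at 15 min and at 1.65 at 120 min, when 67 of 70 were above it. The features that fell ran the other way. Their median was 1.12 log2 units above normal at 15 min, with 21 of 22 above it, and -0.38 at 120 min, with 15 below it. The choice by slope by itself sets the 15 and 120 min values apart. The difference in slope between varieties called 0 features with limma, and 2154 had an unadjusted p under 0.05. The trend count depended on single arrays. It was 0 without Shin-Hong cold 15 min, Shin-Hong cold 120 min, Man-Su cold 60 min or Man-Su cold 120 min, 1 without Man-Su cold 15 min, 11 without Shin-Hong cold 30 min and 28 without Shin-Hong cold 60 min. The trend count was 40 on the deposited values, and 777 with the slope taken per hour. With an array left out, the slope of the steepest rise was 1.35 to 1.64 log2 units per doubling. That of the steepest fall was -1.02 to -0.824, and both features were picked for their slope.

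**Figure D3:**
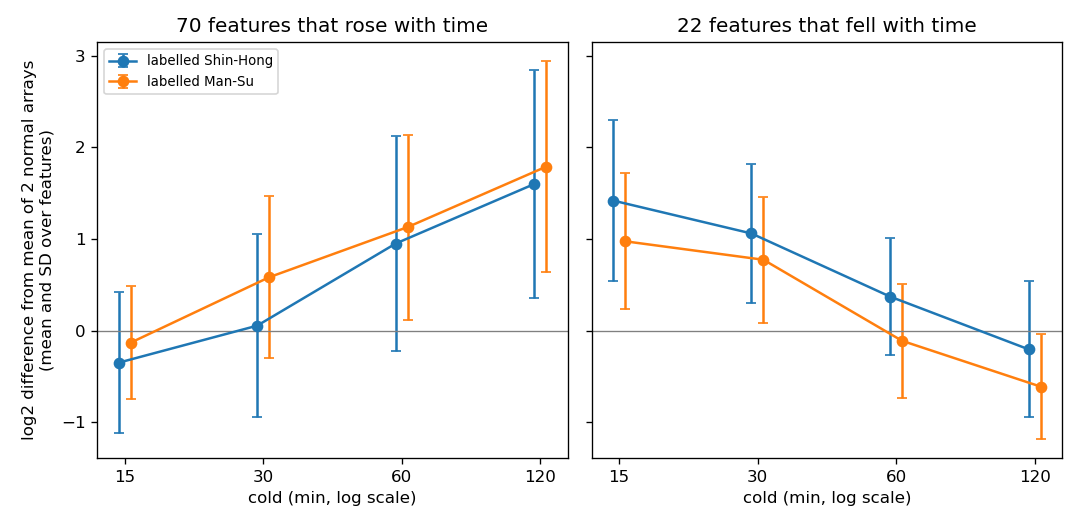
Mean log2 difference from the mean of the 2 normal arrays (y axis) against cold time in min (x axis, log scale) for the 70 features that rose (left) and the 22 that fell (right), by labelled variety; bars are SD over features. The features that rose ended at 1.60 (Shin-Hong) and 1.79 (Man-Su), and those that fell went from 1.42 and 0.97 at 15 min to -0.20 and -0.61 at 120 min.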

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

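The criteria of all tests of explanations in this part were set after the result was seen, while the reading of the 50 markers in the normal arrays was itself planned. Of 16 checks for an array far from the others of its labelled variety, 7 stood out. Chance gives about 1 in 20 for independent checks, which these are not: 4 of the 7 used markers chosen for wide gaps between the cold arrays, and others read the same array again.

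Among the 5 arrays labelled Man-Su, the normal array stood apart with 11.24 log2 units for the markers of Shin-Hong cold and 4.63 for those of Man-Su cold. Among the 5 labelled Shin-Hong, the normal array stood apart with 6.30 and 10.73. The interaction of variety and cold, a test of the difference between the varieties, called 6081 features. Array background of the size seen in the control features is too small for the marker pattern. The 50 markers differed by 5.47 log2 units on average between the normal arrays and the control features by 0.23. These markers were chosen for wide gaps in cold, so this decides nothing on the 6081 calls. The control-level term was not run for the interaction. The markers that kept the labelled direction numbered 0 of 50, as an exchange of variety labels between normal and cold arrays needs, and both normal arrays were out of place. The title letters pair the arrays that way too, so exchanged labels are a candidate explanation; which set carries the wrong names is open. A reversal of the variety differences within 15 min of cold gives the same values and cannot be told apart from an exchange, as each variety has 1 normal array; the 6081 interaction calls with the labels as given and 0 with exchanged labels come from the same values.

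Man-Su cold 30 min stood apart from the other arrays labelled Man-Su in the random-sequence control, 5.63 log2 units both among the 4 cold arrays and among all 5, and in the lowest decile of deposited values, 8.87 among the 4. It also leaned towards the arrays labelled Shin-Hong cold, by 34.4% of the difference at features under 1 log2 unit apart and by 6.71% at those over 4 units apart. RNA of the other variety mixed in is argued against: at 34 features bright in the arrays labelled Shin-Hong cold and dim in the other Man-Su cold arrays, the implied share had a median of 1.56%. Its control features averaged 8.36 log2 units, within the 8.11 to 8.44 of the arrays labelled Shin-Hong cold and above the 7.40 to 7.77 of the other Man-Su cold arrays, so a shared array background may account for part of the lean. A response of Man-Su at 30 min was not tested. Shin-Hong cold 120 min leaned the opposite way, although its control features were high. Its lean was 50.3% at features under 1 log2 unit apart and 8.98% at those over 4 units apart.

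The barcode controls, which were not tested as features and enter the fits through the control-level term alone, averaged 8.55 ± 0.44 log2 units in the 8 cold arrays (SD) and 8.01 in the 2 normal arrays, a difference of 0.54. This was no difference of cold arrays in general: the arrays labelled Shin-Hong cold and Man-Su cold 30 min had 8.65 to 8.98, while Man-Su cold 15, 60 and 120 min had 8.27, 8.05 and 7.82, near the 7.88 and 8.13 of the normal arrays.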

How the results depend on the processing

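The control-level term, the fits without the 2 arrays that leaned to the other variety (Man-Su cold 30 min, Shin-Hong cold 120 min) and other choices joined to exchanged labels were chosen after seeing the data; the cause of a moved count was not tested unless stated. Counts of called features are given for 15, 30, 60, 120 min and all cold times against normal, from 1, 2, 3, 114 higher with 9 lower, and 906. Exchanged labels gave 1447, 3434, 723, 3457 and 7137. Leaving out the dimmest 25% gave 184, 251, 43, 634 and 1941, and an intensity trend in the prior 131, 202, 65, 511 and 1818. The control-level term gave 0 for each. Without the variety block the counts were 16, 5, 29 and 561 for 30, 60, 120 min and all cold times. At 30 min the deposited values and median centring gave 1 each, and at 120 min median centring gave 42. Leaving out each array gave 0 to 6299, 0 to 10244, 0 to 5725, 0 to 6260 and 0 to 10527, the highest in each case without the array labelled Man-Su normal. A fit without a normal array sets the cold arrays of 1 labelled variety against its lone normal array, so its count also carries the labels. Without the leaning arrays all cold times gave 0.

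Varieties over 10 arrays, 0 features, became 12387 with exchanged labels, and 0 to 12195 with each array left out, the highest without either normal array. Varieties in cold, 12195, gave 3242 at 2-fold, 534 with the control-level term, 19773 without the leaning arrays, and 2989 to 14569 with each array left out. The time trend, 92, gave 40 on deposited and on median-centred values, 307 without the dimmest 25%, 460 with the intensity trend, 7 at 2-fold per doubling, 0 without the variety block, 777 with minutes, and 0 to 126 with each array left out. The interaction of variety and cold, 6081, gave 3775 without the dimmest 25%, where fewer features were tested, 0 with exchanged labels and 15896 without the leaning arrays. It gave 3918 to 12040 with each cold array left out, and cannot be fitted without either normal array. The interaction with time gave 0 in every setting run.

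With exchanged labels, all cold times (7137) gave 33 with the control-level term, 2820 without the leaning arrays, and 1073 to 7577 with each array left out; the split was 3862 higher to 3275 lower, and 4222 to 1820 on deposited values. Varieties (12387) gave 1386 with the control-level term and 5303 to 12195 with each array left out. Of the alternatives run on 12 single features, 128 kept the call, 73 lost it and none turned its direction. Each feature of the varieties in cold kept the call in 15 and lost it in 0. The features of all cold times and of the time trend each kept it in 6 to 10 and lost it in 6 to 11. These tallies do not count separate checks. For the varieties in cold, leaving out either array of a cold time gave the same fit. The series-wide table held nearly the same values, and these variety differences were too large to fail the 2-fold threshold. The setting without the dimmest features gave no value for the features of the varieties in cold or for some of the time trend. That setting is not counted for them. The series-wide table moved no count by over 1.5 times. The gene list alternatives were not run, as no feature had a name. Dim features limit the folds where one side lies under the random-sequence control. A bound on the signal is given only for the features with the largest fitted variety differences. The marker gaps and the counts at a fold threshold have no such floor.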

Other observations

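The tests of the time course against normal, of the order of times, of the 10-array variety split and of exchanges within times were chosen after related values were seen, and the split of the 8 cold arrays before. At 15, 30, 60 and 120 min, 1, 2, 3 and 114 features were called higher against normal with the labels as given, and 9 lower at 120 min. With exchanged labels 1447, 3434, 723 and 3457 were called in all. The high counts at 30 and 120 min fall at the times of the arrays that leaned towards the other variety, Man-Su cold 30 min and Shin-Hong cold 120 min. In the 7137 features called with exchanged labels for the average of the cold times, the median ratio of the 15 min to the 120 min change was 0.910 in the arrays labelled Shin-Hong cold and 0.976 in those labelled Man-Su cold, each taken against the normal array with its marker profile. The choice of these features by that average and the shared normal array both draw the ratio towards 1, so it does not show how much of the change was present at 15 min. With exchanged labels, 92.5% of the 6042 features called on the deposited values were called in the same direction after quantile normalization. The largest decile gap was -0.11 log2 units (normal minus cold), so the 2 scalings were close and much overlap was likely. The overlap is thus weak evidence against different value distributions of normal and cold arrays as the cause of these calls. Scaling did act on the falls, 1820 on the deposited values and 3275 after quantile normalization. A separate run of the normal arrays may give a constant shift; the ratio of 0.976 decides nothing on it, and run and condition cannot be told apart with both normal arrays on one side. An early response to cold, which the design names, stays open and untested. Across features, the change at 30 and 60 min against normal had a correlation of 0.025 with the change from 15 to 120 min.

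The change from 15 to 120 min had a correlation across features of 0.294 between the varieties, that from 15 to 60 min 0.210 and that from 15 to 30 min -0.153. These changes share the 15 min array within a variety and no array between varieties. The 30 and 120 min values each include an array that leaned towards the other variety, and the 60 min value does not.

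For the 12195 features called between varieties in cold, 32 of the splits of the 8 arrays into 4 and 4 could be fitted with time as a block, and 1, the real one, gave as many; the highest other gave 0. The fit pairs the arrays by time, and exchanges of the varieties within times number 8, too few for a share under 0.05. The real one gave 12195 and the highest other 0. Any other split or exchange leaves part of the variety difference in the error, which favours 0 calls. These counts thus show little beyond a grouping of the cold arrays by labelled variety, whatever its cause. For the 92 features of the time trend, 1 of 100 orders of the times within varieties, the real one, gave as many, and the highest other gave 2. Over all 10 arrays the real split gave 0 features, which each of the 100 splits drawn must equal or exceed, so this count tests nothing. The highest other, 12387, was the split with the labels of the normal arrays exchanged, and the highest of the rest was 6074. What the arrays of that last split have in common was not examined.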
